A study of Homo sapiens with 15 samples.

How the data were processed

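RNA of VCaP cells was profiled on 15 arrays of the Illumina HumanHT-12 v4 BeadChip, 3 for each of 5 groups. The groups were a non-targeting siRNA, ERG siRNA 1, ERG siRNA 2, DMSO and WP1130. Per the labels' protocols, total RNA was column-purified and made into biotin-labelled cRNA, 72 h after transfection with an ERG siRNA or after 24 h with WP1130. The dose of WP1130 and the times of both control groups are not given in the sources used here. Each array was assigned to its group by its treatment label.

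The deposited non-normalized table gives, per the file headers, an intensity for each of 47322 probes on each array, on a linear scale. Beside it stands a deposited detection p-value, which sets the probe against the negative control beads of the same array and runs in steps that imply 770 such beads. GenomeStudio is named in the submitters' processing notes, without a version or a role. The lowest intensity was 81.0 and background medians per array were 101 to 116, so no background subtraction is visible in the values. A second deposited table, the authors' processed values, holds an intensity per probe from 2.08 to 26353 on a linear scale. On 15 of 15 arrays its probe ranks equalled those of the non-normalized table, and its sorted values matched those of the first array within 1%, with a median of 9.50 in each column. These values are thus scaled to 1 common distribution, but the method of background correction and scaling is not given in the sources used here. They served as an alternative. There were 0 pairs of arrays with identical values, and 0 columns that could not be mapped to a sample.

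Intensities were background-corrected with the normexp model, with negative controls inferred from the detection p-values and an offset of 16, quantile normalized between arrays and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. A probe was kept if its detection p was under 0.05 on at least 3 of the 15 arrays, which left 23281 probes. Gene symbols came from a platform annotation, in which 30113 probes had 1 gene symbol, 8 had several and 17201 were not listed. Of the probes past the filter, 17078 had 1 symbol, 3 had several and 6200 were not listed. Symbols were compared with a current gene table through the gene ID, and 0 of them had to be updated. For each of 12744 genes the probe with the highest mean over all arrays stood for the gene; 3351 genes had more than 1 probe past the filter. Where other probes of a named gene disagreed, the text says so. The single KLK3 probe was detected on 1 array and the single probes of FLI1 and ETV1 on 0 arrays, so these genes did not pass the filter.

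A 5-group limma model was fitted to all 15 arrays, so that all groups shared 1 estimate of the spread (10 residual degrees of freedom). Contrasts were each ERG siRNA against the non-targeting siRNA, their mean against the non-targeting siRNA, WP1130 against DMSO, ERG siRNA 2 against ERG siRNA 1, and the WP1130 effect minus the mean ERG siRNA effect. Tests were moderated (eBayes) and two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Changes are log2 differences of group means ± SE. Where a probe was undetected on every array of 1 group, its change is a bound, given as at least N-fold. The bound sets the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value of any detected probe. The number of arrays limits the precision: the median SE was 0.10 for contrasts of 2 groups, 0.087 for the mean of both siRNAs and 0.13 for the difference between effects.

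Of 35 gene lists, 34 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, adjusted over the 34 lists of a comparison, and again with a correlation estimated for each list. The test fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, was run beside it. The lists were androgen-induced genes, androgen-lowered genes, genes linked to ERG-positive prostate cancer, luminal epithelium, basal epithelium, mesenchymal and EMT genes, neuroendocrine genes, fibroblast and smooth muscle markers, blood cell markers, endothelial markers, DNA replication and G1/S genes, mitosis and G2/M genes, heat shock chaperones, endoplasmic reticulum chaperones and ERAD, ATF4 and integrated stress response, NRF2 and oxidative stress, proteasome subunits, ubiquitin and deubiquitinase genes, metallothioneins, p53 target genes, apoptosis regulators, interferon response, NF-kB and inflammatory response, immediate early genes, cholesterol biosynthesis, fatty acid synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosome biogenesis, ribosomal proteins, Wnt pathway, Notch pathway, extracellular proteases and invasion, ETS transcription factors, and autophagy and lysosome. Together they held 836 entries, of which 663 were measured and 4 matched no symbol. For endothelial markers only VWF, ENG and EGFL7 were measured, so that list was not tested. Some genes stand in several lists, such as ADAMTS1 in 3.

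The gene lists, the main design, the other settings and the rule for named genes were fixed before the data were examined. The rule names the focus genes ERG, TMPRSS2, KLK3, USP9X, USP5, USP14, UCHL1, UCHL5, FLI1 and ETV1 where measured; a further gene is not reported here. It also names the 8 largest rises and the 8 largest falls of a main comparison among genes past the threshold whose treated and control arrays do not overlap. For the knockdown such a gene had to pass with each siRNA alone in the same direction. Of each list, up to 2 members with the largest rise and 2 with the largest fall may be named, and for both difference tests the 3 largest in each direction. Placeholder symbols were left out.

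Both siRNAs were compared with the same 3 non-targeting arrays, so the correlation of unchanged groups sharing such controls was simulated in 100 draws. The pipeline was tested on simulated data with 200 of 12744 genes changed. Changes of 1 and 2 on the log2 scale were recovered at 100% in every contrast. A change of 0.5 was recovered at 75.0% for ERG siRNA 1, 79.4% for ERG siRNA 2 and for the mean of both, 82.4% for WP1130, 67.6% for ERG siRNA 2 against ERG siRNA 1 and 36.8% for the difference between effects. False calls made up 2.48 to 7.11% of all calls. A shift of 0.5 simulated on the proteasome list for WP1130 against DMSO was called by camera (adjusted p = 1.79e-82), with 0 other lists called. The simulated genes varied independently, so false calls of lists whose genes vary together were not tested. In the data the estimated correlation was, for example, 0.11 for androgen-induced genes and 0.40 for metallothioneins.

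The results were repeated with quantile normalization without background correction, median scaling in place of quantile normalization, and the authors' processed values. The filter was left out or made stricter (p under 0.01 on all 3 arrays of a group). The model was fitted with the replicate number as a block, with only the groups compared, and with the trend and robust options of eBayes. Genes were represented by the mean of their probes, or every probe was tested on its own. Other thresholds were an adjusted p under 0.01 and a minimum change of 1.5-fold. Each array of the compared groups was left out in turn, with the normalization and filter of all arrays kept. Chosen after seeing the data were the alternative with no scaling between arrays, the test of the ERG siRNA gene sets in WP1130, and the comparison of DMSO with the non-targeting siRNA. A block for the slide was not run, because slide positions are not given in the sources used here.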

Results

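The series holds 15 expression arrays of VCaP cells, an established prostate cancer line that carries the TMPRSS2-ERG gene fusion and responds to androgen. Cells received a non-targeting siRNA, 1 of 2 siRNAs against ERG, the vehicle DMSO, or WP1130, a small-molecule inhibitor of several deubiquitinases including USP9X, with 3 arrays per group. The design asks which transcripts depend on ERG, the ETS transcription factor that the fusion places under androgen control, and whether the deubiquitinase inhibitor acts on transcripts like the loss of ERG. Mean raw intensity per array was 427 ± 28.3 (SD, n = 3) with the non-targeting siRNA, 424 ± 11.9 with ERG siRNA 1, 413 ± 27.2 with ERG siRNA 2, 417 ± 19.4 with DMSO and 311 ± 5.21 with WP1130. The WP1130 arrays stood at 74.6% of the DMSO arrays (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). Between 18460 and 21220 probes were detected per array, and replicate arrays correlated at 0.993 to 0.997 over the 12744 genes tested. The labels do not say that replicate arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

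ERG, the gene targeted by the siRNAs, was lower with both of them and with WP1130. Its log2 intensity was 6.0 ± 0.15 (SD, n = 3) with the non-targeting siRNA, 5.30 ± 0.41 with ERG siRNA 1 and 5.22 ± 0.39 with ERG siRNA 2. With DMSO it was 6.30 ± 0.05 and with WP1130 5.76 ± 0.09. The change was -0.71 ± 0.18 (SE) with ERG siRNA 1 (limma adjusted p = 0.019). This left 61.3% of the normalised intensity (95% confidence interval 47.7 to 78.8). With ERG siRNA 2 it was -0.78 ± 0.18 (adjusted p = 0.0079), leaving 58.3% (45.4 to 75.0), and for the mean of both siRNAs -0.74 ± 0.16 (adjusted p = 0.0038). With WP1130 it was -0.54 ± 0.18 (adjusted p = 0.020), leaving 68.8% (53.5 to 88.5). The probe was dim, with raw means of 166, 138, 136, 179 and 129 in the 5 groups in the order given, against background medians of 113, 112, 111, 111 and 103, and it was detected on 14 arrays, all but ERG siRNA 2 replicate 2. The ERG call for ERG siRNA 1 was lost with the authors' processed values (-1.10, adjusted p = 0.055) and without non-targeting siRNA replicate 1 (-0.64, 0.074), non-targeting siRNA replicate 2 (-0.69, 0.057), ERG siRNA 1 replicate 1 (-0.56, 0.090) or ERG siRNA 1 replicate 3 (-0.62, 0.080). For WP1130 it was lost with median scaling (-0.20, adjusted p = 0.37), with the authors' processed values (-0.73, 0.085), and without DMSO replicate 3 (-0.51, 0.055), WP1130 replicate 1 (-0.50, 0.057) or WP1130 replicate 2 (-0.52, 0.051). Without background correction the ERG changes shrank to -0.24, -0.27 and -0.22 with siRNA 1, siRNA 2 and WP1130, and with no scaling between arrays the change with WP1130 was -0.99. The other 2 ERG probes were detected on 2 arrays each and did not pass the filter; their changes for the mean of both siRNAs were -0.26 and -0.09, and with WP1130 0.40 and -0.06. Which part of ERG each probe measures was not analysed here.

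**Figure D1:**
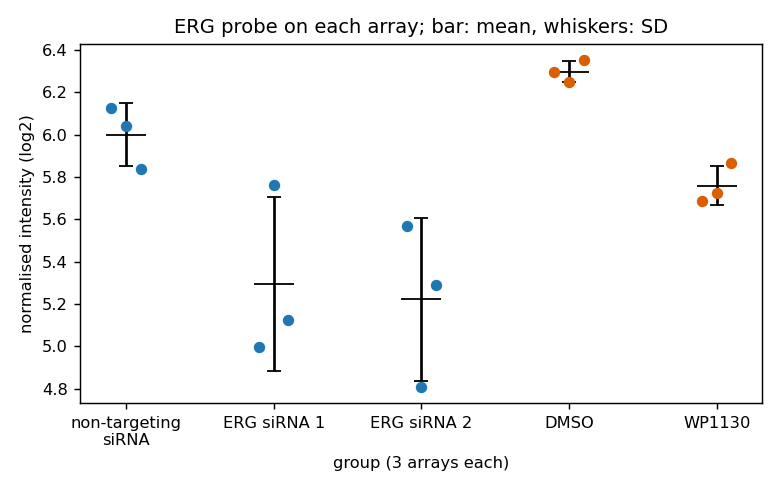
Normalised log2 intensity of the ERG probe (y axis) on each of the 3 arrays of the 5 groups (x axis), with a bar at the group mean and whiskers for the SD. Means were 6.0 with the non-targeting siRNA against 5.30 and 5.22 with the ERG siRNAs, and 6.30 with DMSO against 5.76 with WP1130.

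After ERG knockdown the largest rise was that of HEPACAM2, an immunoglobulin-family adhesion molecule, at 2.59 ± 0.12 (log2 ± SE, mean of both siRNAs, 6 arrays against 3). CFAP69, a cilia and flagella protein, rose by 1.98 ± 0.09, CCN3, a secreted matricellular protein, by 2.0 ± 0.10, and LRRTM4, a synaptic adhesion protein, by 1.94 ± 0.10. The ciliary transport gene BBS4 rose by 1.78 ± 0.08 and ATOH1, a transcription factor of secretory and sensory cells, by 1.74 ± 0.13. RLN1, which encodes the hormone relaxin and has the near-identical copy RLN2, and MYLK, the myosin light chain kinase, were not detected with the non-targeting siRNA. They rose at least 2.61-fold and at least 2.57-fold, and a second MYLK probe gave 0.44. ARHGDIB fell most; it fell by 2.18 ± 0.09. PLA1A, a phospholipase, fell by 1.88 ± 0.08, MGP, an inhibitor of calcification, fell by 1.74 ± 0.10, and PAPSS2, which makes the sulfate donor for sulfation, fell by 1.69 ± 0.11. ANXA1, a phospholipid-binding annexin, fell by 1.59 ± 0.10, BRINP1 fell by 1.58 ± 0.09, the atypical chemokine receptor ACKR3 fell by 1.55 ± 0.09, and the Wnt ligand WNT2 fell by 1.52 ± 0.08. TMPRSS2, the androgen-induced protease whose promoter drives the fusion, rose by 1.32 ± 0.07 (adjusted p = 1.0e-08); whether its probe also measures the fusion transcript was not tested. For the 16 other genes the limma adjusted p lay between 7.5e-10 and 1.65e-07. By the rule that chose them, all 6 knockdown arrays lay beyond all 3 control arrays.

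In all, 2580 of 12744 genes changed with the mean of both ERG siRNAs, 1359 up and 1221 down, of which 56 rose and 41 fell by at least 2-fold. ERG siRNA 1 alone changed 1657 genes (860 up, 797 down) and ERG siRNA 2 changed 2372 (1277 up, 1095 down). With both siRNAs, 713 genes rose and 605 fell, and 1 gene passed in opposite directions. Requiring at least 1.5-fold left 374 genes for the mean, 356 and 467 for the single siRNAs, and 298 for both. Without scaling between arrays 1402 genes passed for the mean, 842 and 1187 for the single siRNAs and 674 for both.

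Androgen-induced genes rose together after ERG knockdown. Of 23 measured, 16 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.38. Camera gave an adjusted p = 1.4e-11, and an adjusted p = 0.0098 with an estimated correlation. They included the extracellular protease ADAMTS1 (1.66), the prostate transporter SLC45A3 (1.43) and TMPRSS2. The list was also higher with DMSO than with the non-targeting siRNA (median 0.29, adjusted p = 0.013, but 0.31 with an estimated correlation). A level peculiar to the shared non-targeting arrays may thus contribute to the rise. Among 5 androgen-lowered genes, 3 fell (3 adjusted over the list alone), among them the androgen-conjugating enzymes UGT2B17 (-0.70) and UGT2B15 (-0.69). That list passed with the preset correlation (adjusted p = 0.026) and not otherwise (adjusted p = 0.091 with an estimated correlation). Genes linked to ERG-positive prostate cancer fell: 14 of 26 fell and 3 rose, with the same counts adjusted over the list alone, a median of -0.27, an adjusted p = 1.1e-06, and an adjusted p = 0.0043 with an estimated correlation. ARHGDIB and PLA1A belong to it, as does ADAMTS1, which rose. Luminal epithelium genes had 7 up and 1 down of 15 (the same adjusted over the list alone; adjusted p = 0.011, but adjusted p = 0.099 with an estimated correlation). The keratin KRT19 (0.78) and the secreted trefoil factor TFF3 (0.49) rose.

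Cell cycle genes fell with the ERG siRNAs. Of 29 DNA replication and G1/S genes 18 fell and 0 rose (23 and 0 adjusted over the list alone; median -0.34, adjusted p = 2.35e-11, and adjusted p = 0.0082 with an estimated correlation). Among them were the replication licensing factor CDT1 (-0.55) and UHRF1 (-0.52), which maintains DNA methylation. Of 32 mitosis and G2/M genes 18 fell and 0 rose (22 and 0 adjusted over the list alone; median -0.24, adjusted p = 4.65e-09, and adjusted p = 0.014 with an estimated correlation). Among them were cyclin B1, CCNB1 (-0.52), and the kinetochore protein CENPF (-0.47). Mitosis genes were also lower with DMSO than with the non-targeting siRNA (median -0.91, camera adjusted p = 5.3e-36). Replication genes were too (median -0.22, adjusted p = 4.2e-06, but 0.12 with an estimated correlation). A level peculiar to the shared non-targeting arrays may thus contribute to the falls of both lists. Ribosome biogenesis genes also fell, 12 of 23 with 0 up (17 and 0 adjusted over the list alone; median -0.25, adjusted p = 2.8e-07, and adjusted p = 0.0037 with an estimated correlation). NIP7 was at -0.39. In the Notch pathway 7 of 12 genes fell and 0 rose (7 and 0 adjusted over the list alone; median -0.29, adjusted p = 0.0051, and adjusted p = 0.030 with an estimated correlation). The target HES1 (-0.60) and the receptor NOTCH1 (-0.49) were among them.

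Cholesterol biosynthesis genes rose: 13 of 19 rose and 0 fell (16 up and 1 down adjusted over the list alone), with a median of 0.37, an adjusted p = 3.6e-09, and an adjusted p = 0.0015 with an estimated correlation. SC5D, a late sterol desaturase, rose by 0.82, and MSMO1, a sterol oxidase, by 0.67, with other MSMO1 probes between -0.33 and 0.80. In fatty acid synthesis 4 of 13 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.071 with an estimated correlation). The elongase ELOVL6 (0.36) rose. With no scaling the fatty acid list lost its call (adjusted p = 0.082). In autophagy and lysosome 8 of 22 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.099 with an estimated correlation). The sialidase NEU1 was at 0.82, MAP1LC3A at 0.55 and the conjugation enzyme ATG7 at -0.66. With every probe on its own this list's direction turned (median -0.02, adjusted p = 0.51). Proteasome subunits had 3 of 30 up and 0 down (2 and 0 adjusted over the list alone; adjusted p = 0.046, and adjusted p = 0.33 with an estimated correlation). The proteasome call was also lost with median scaling (adjusted p = 0.17), the stricter filter (0.065), the mean of a gene's probes (0.14), no scaling (0.32), and without non-targeting siRNA replicate 1 (0.13), non-targeting siRNA replicate 2 (0.099), ERG siRNA 1 replicate 3 (0.088), ERG siRNA 2 replicate 2 (0.078) or ERG siRNA 2 replicate 3 (0.056). In ATF4 and integrated stress response 8 of 28 fell and 1 rose (9 and 3 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.15 with an estimated correlation). The lipoprotein receptor VLDLR was at -1.20 and the pseudokinase TRIB3 at -0.50. The call was lost with every probe on its own (adjusted p = 0.48).

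The other 21 lists did not pass with the ERG siRNAs. Among ETS transcription factors, which include ERG, 4 of 17 rose and 3 fell (adjusted p = 0.82), with ETS2 at -1.03, ELK4 at 0.85 (its other probes 0.18 to 0.47) and ELF5 at 0.78. In the Wnt pathway 2 of 13 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.78); the receptors FZD8 (-1.03) and FZD4 (-1.01) fell, and the ligand WNT5A, not detected with the non-targeting siRNA, rose at least 1.76-fold. Fibroblast and smooth muscle markers (2 up, 1 down of 6; adjusted p = 0.57) and mesenchymal and EMT genes (1 up, 2 down of 8, or 2 and 2 adjusted over the list alone; adjusted p = 0.82) shared smooth muscle actin ACTA2 (-1.34) and TAGLN (0.78). Of p53 target genes 2 of 16 rose and 3 fell (adjusted p = 0.85), with the cell cycle inhibitor CDKN1A at 0.50 (its other probe 0.01) and the death receptor FAS at -0.85. Immediate early genes had 4 up and 2 down of 22 (adjusted p = 0.90), with DUSP1 at 0.47 and MYC at -0.47. Hypoxia and glycolysis had 3 up and 7 down of 28 (3 and 9 adjusted over the list alone; adjusted p = 0.21), interferon response 2 up and 3 down of 23 (adjusted p = 0.82), with HERC5 at 1.04, and heat shock chaperones 3 up and 2 down of 25 (adjusted p = 0.82), with HSPB1 at 0.60 and HSPA4 at -0.40. Ribosomal proteins had 0 up and 2 down of 35 (0 and 1 adjusted over the list alone; adjusted p = 0.49), and as a list passed as lower with median scaling (median -0.13, adjusted p = 0.0036) and with no scaling (-0.10, 0.020). The counts up and down were 1 and 4 of 47 for oxidative phosphorylation (adjusted p = 0.78), 1 and 3 of 25 for endoplasmic reticulum chaperones and ERAD (2 and 7 adjusted over the list alone; 0.78), 2 and 2 of 22 for NRF2 and oxidative stress (0.78), 1 and 1 of 22 for ubiquitin and deubiquitinase genes (0.78) and 2 and 1 of 17 for apoptosis regulators (0.78). They were 0 and 2 of 8 for metallothioneins (adjusted p = 0.79), 0 and 1 of 16 for NF-kB and inflammatory response (0.50), 1 and 1 of 10 for extracellular proteases and invasion (2 and 1 adjusted over the list alone; 0.70) and 1 and 0 of 11 for neuroendocrine genes (0.28). The same counts were 1 and 1 of 5 for basal epithelium (adjusted p = 0.82) and 0 and 2 of 7 for blood cell markers (0.23). The list median and the test differed in sign for mesenchymal genes (median 0.06). Without background correction the medians shrank for androgen-lowered genes (-0.37), luminal epithelium (0.076), Notch (-0.11) and autophagy genes (0.087). Luminal genes stood at 0.091 with median scaling and at 0.12 with no scaling or with every probe on its own, Notch genes at -0.14 with the mean of a gene's probes, and autophagy genes at 0.096 with no filter. Of the 102 changed genes that the rule named in this comparison, 40 had changes over 1.5 times smaller without background correction. Of the 13 lists that passed with the preset correlation, 7 passed with an estimated correlation, and fry called 22 of the 34.

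Both ERG siRNAs gave similar changes across genes, with a Pearson r of 0.868 (Spearman 0.792) over 12744 genes, which are not independent replicates. Unchanged groups sharing the same 3 control arrays gave a simulated r of 0.50 (Spearman 0.476). The covariance of the changes was 0.0566 against a simulated 0.00621, a difference of 0.0504, and 79.3% of genes had the same sign against a simulated 66.7%. Independent lists of these sizes would share 86.2 risen and 68.5 fallen genes, against 713 and 605 observed. The controls cannot be split into parts of at least 2 arrays each, so part of the excess may come from the shared controls. A direct comparison of ERG siRNA 2 with ERG siRNA 1 called 15 genes, 8 up and 7 down. GULP1, an engulfment adaptor, fell with ERG siRNA 1 (-1.03) and not with ERG siRNA 2 (0.04), a difference of 1.07 ± 0.10 (limma adjusted p = 0.00039). The matrix glycoprotein THBS1 fell with both, at -1.49 with ERG siRNA 1 and -0.84 with ERG siRNA 2 (difference 0.65 ± 0.08, adjusted p = 0.0024, but 0.068 with only those groups fitted and 0.091 with no scaling). RLN1, which was detected with both ERG siRNAs and not with the non-targeting siRNA, was lower with ERG siRNA 2 than with ERG siRNA 1 (difference -0.96 ± 0.12, adjusted p = 0.0026, but 0.096 with the authors' processed values and 0.068 with only those groups fitted). The microRNA gene MIR92A2 was undetected with ERG siRNA 1 and at least 1.45-fold higher with ERG siRNA 2 (adjusted p = 0.0053, but 0.059 without background correction, 0.11 with the authors' processed values and 0.077 with only those groups fitted). The decarboxylase DDC differed by -0.59 ± 0.09 (adjusted p = 0.015, but 0.12 with only those groups fitted or with no scaling). Its call was also lost without ERG siRNA 1 replicate 2 (-0.56, 0.12) or 3 (-0.53, 0.094), or without ERG siRNA 2 replicate 1 (-0.60, 0.078), 2 (-0.60, 0.067) or 3 (-0.58, 0.070). The centriole gene SASS6 differed by -0.58 ± 0.10 (adjusted p = 0.044), and lost its call without any 1 of the 6 arrays of ERG siRNA 1 and ERG siRNA 2 (-0.63 to -0.53, adjusted p 0.094 to 0.18). The SASS6 call was lost as well with the authors' processed values (adjusted p = 0.10), every probe on its own (0.094), the mean of its probes (-0.39, 0.16), no filter (0.063), no scaling (0.16), only those groups fitted (0.077) and the replicate number as a block (0.059). The count was 58 without background correction, 36 with trend and robust options, 3 with no scaling and 1 with only those groups fitted, and 9 to 14 with 1 array left out, with 9 without ERG siRNA 1 replicate 2 or ERG siRNA 2 replicate 1. Mitosis and G2/M genes (median -0.10, adjusted p = 3.4e-05), ribosome biogenesis (-0.10, 0.0028) and metallothioneins (-0.17, 0.00035) were lower and androgen-induced genes higher (0.09, 0.0042) with ERG siRNA 2 than with ERG siRNA 1, but 0 lists passed with an estimated correlation, where the adjusted p was 0.17, 0.13, 0.54 and 0.54.

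With WP1130 the small heat shock protein CRYAB, the inducible chaperone HSPA6, heme oxygenase HMOX1 and FOS, part of the AP-1 complex, rose from levels that were undetected with DMSO. They rose at least 196-fold, at least 174-fold, at least 85.2-fold and at least 42.8-fold; HSPA6 has the near-identical copy HSPA7. The stress-induced transcription factor ATF3, detected on 1 of 3 DMSO arrays, rose by 6.26 ± 0.13 (log2 ± SE, 3 arrays against 3; other probe 1.62), the stromelysin MMP10 by 6.24 ± 0.14, HSPA1A, whose near-identical copy is HSPA1B, by 6.03 ± 0.14, and HSPB1 by 5.80 ± 0.09. D2HGDH, a mitochondrial hydroxyglutarate dehydrogenase, fell by 2.02 ± 0.09, the small nucleolar RNA SNORA22 fell by 1.76 ± 0.13, and the mitochondrial methionyl-tRNA synthetase MARS2 fell by 1.71 ± 0.09 (other probe -0.13). HILPDA, a lipid droplet protein, fell by 1.70 ± 0.08, MYC fell by 1.67 ± 0.09 (other probe -1.50), FJX1 fell by 1.65 ± 0.11, the Cajal body RNA SCARNA12 fell by 1.63 ± 0.15, and the zinc finger gene ZNF566 fell by 1.55 ± 0.12 (other probe -0.23). For these 16 genes the limma adjusted p lay between 7.7e-18 and 2.0e-07. Whether the SNORA22 and SCARNA12 probes measure the mature small RNAs was not tested.

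In all, 7519 genes (59.0%) changed with WP1130, and of these 2790 rose and 4729 fell, so that 37.1% of the changed genes rose. The split depended on the scaling: with median scaling 5204 rose and 3172 fell (62.1% up), and with no scaling 1108 rose and 9321 fell (10.6% up). The median change of all genes was -0.12, 0.14 with median scaling and -0.65 with no scaling, and the changes given here are relative to the quantile-normalized arrays. Among changes of at least 2-fold, 907 genes rose and 197 fell, and at 1.5-fold 1569 rose and 1506 fell (51.0% up). Tested on their own, 11945 of the probes passed.

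Heat shock chaperones rose almost throughout with WP1130, 24 of 25 with 0 down (24 and 0 adjusted over the list alone; median 2.23, adjusted p = 1.2e-22, and adjusted p = 0.0011 with an estimated correlation). Of 22 immediate early genes 18 rose and MYC fell (the same adjusted over the list alone; median 3.12, adjusted p = 4.15e-14, and adjusted p = 0.0012 with an estimated correlation). NF-kB and inflammatory genes had 11 up and 0 down of 16 (the same adjusted over the list alone; median 1.04, adjusted p = 1.5e-06, and adjusted p = 0.0024 with an estimated correlation). The chemokines CXCL8 (3.54, other probe 5.52) and CCL2 (2.26) rose. In ATF4 and integrated stress response 17 of 28 rose and 8 fell (17 and 9 adjusted over the list alone; median 0.55, or -0.11 with no scaling, adjusted p = 3.1e-05, and adjusted p = 0.034 with an estimated correlation). The phosphatase subunit PPP1R15A, which reverses the block of translation, rose by 4.62, while the amino acid transporter SLC7A1 (-0.60) and the tRNA synthetase EPRS1 (-0.46) fell. With every probe on its own the ATF4 call was lost (adjusted p = 0.39). Extracellular proteases and invasion had 8 up and 2 down of 10 (the same adjusted over the list alone; median 1.57, adjusted p = 0.00024, and adjusted p = 0.011 with an estimated correlation). The collagenase MMP1, undetected with DMSO, rose at least 4.01-fold. In the Notch pathway 7 of 12 rose and 2 fell (the same adjusted over the list alone; median 0.31, or -0.19 with no scaling, adjusted p = 0.0046, and adjusted p = 0.034 with an estimated correlation). The ligand DLL1 was at 4.70, the target HEY1 at 3.27 (other probe 0.91) and the ligand JAG2 at -0.55. Autophagy and lysosome had 13 up and 3 down of 22 (the same adjusted over the list alone; median 0.27, or -0.48 with no scaling, adjusted p = 0.0027, and adjusted p = 0.044 with an estimated correlation). MAP1LC3B was at 1.52. The autophagy call was lost with median scaling (adjusted p = 0.084), with no scaling (0.49) and with every probe on its own (0.39). Ribosome biogenesis genes fell, 21 of 23 with 1 up (the same adjusted over the list alone; median -0.63, adjusted p = 2.4e-05, and adjusted p = 0.0061 with an estimated correlation). The RNA polymerase I subunit POLR1B (-1.44) and BYSL (-1.15) fell. Without background correction the medians of NF-kB (0.51), protease (0.58), Notch (0.19) and ribosome biogenesis genes (-0.42) shrank. With no filter those of NF-kB (0.43), protease (0.73) and Notch genes (0.11) did, and NF-kB genes stood at 1.75 with the stricter filter. With no scaling the medians were 0.53 for NF-kB, 0.97 for protease and -1.31 for ribosome biogenesis genes, and with median scaling 0.61 for Notch genes. With undetected members at their bound, the medians were 2.23 for heat shock, 3.10 for immediate early, 1.01 for NF-kB, 1.25 for proteases and 0.18 for Notch genes.

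A further 8 lists passed with WP1130 at the preset correlation and not with an estimated one. Androgen-induced genes fell, 17 of 23 with 5 up (the same adjusted over the list alone; median -0.62, adjusted p = 0.025, and adjusted p = 0.28 with an estimated correlation). The kinase CAMKK2 (-1.22) and SLC45A3 (-0.97) fell, whereas the transcription factor MAF (1.80) and ADAMTS1 (1.66) rose, and the list's call was lost with no scaling (adjusted p = 0.064). DNA replication and G1/S genes fell, 21 of 29 with 1 up (the same adjusted over the list alone; median -0.42, adjusted p = 0.0013, and adjusted p = 0.14 with an estimated correlation). The uracil glycosylase UNG (-1.0) and the helicase subunit MCM5 (-0.78) fell. Oxidative phosphorylation had 30 down and 0 up of 47 (32 and 0 adjusted over the list alone; median -0.22, adjusted p = 0.0046, and adjusted p = 0.26 with an estimated correlation). Cytochrome c, CYCS (-0.91), and NDUFS1 (-0.88) fell. With every probe on its own the direction of this list's test turned (adjusted p = 0.43), with a median of -0.07. NRF2 and oxidative stress genes had 13 up and 6 down of 22 (13 and 7 adjusted over the list alone; median 0.60, or -0.04 with no scaling, adjusted p = 0.0012, and adjusted p = 0.12 with an estimated correlation). The transporter ABCC3 was at 2.29 and PGD at -0.53. Proteasome subunits had 15 up and 3 down of 30 (the same adjusted over the list alone; median 0.17, or -0.47 with no scaling, adjusted p = 0.0080, and adjusted p = 0.20 with an estimated correlation). PSMD12 was at 1.34 and PSMB4 at -0.65. Metallothioneins had 6 up and 0 down of 8 (the same adjusted over the list alone; median 0.56, or -0.10 with no scaling, adjusted p = 0.0046, and adjusted p = 0.26 with an estimated correlation). MT1G was at 1.83. Luminal epithelium genes had 6 up and 3 down of 15 (the same adjusted over the list alone; median 0.22, or -0.44 with no scaling, adjusted p = 0.028, and adjusted p = 0.18 with an estimated correlation). KRT19 (2.39) and CLDN4 (1.16) rose, while the prostate lineage factors FOXA1 (-0.71) and HOXB13 (-0.37) fell. Interferon response had 11 up and 4 down of 23 (the same adjusted over the list alone; median 0.23, or -0.37 with no scaling, adjusted p = 0.032, and adjusted p = 0.18 with an estimated correlation). ISG20 was at 3.63 and OAS1 at 2.07, and the list lost its call without WP1130 replicate 2 (adjusted p = 0.051). With no scaling the proteasome (adjusted p = 0.80), metallothionein (0.058) and luminal (0.078) calls were lost. With median scaling the luminal call was lost too (adjusted p = 0.13), and the medians were 0.35 for luminal, 0.32 for proteasome, 0.42 for interferon and -0.067 for oxidative phosphorylation genes. Without background correction luminal genes stood at 0.093 and interferon genes at 0.10 (0.080 with no filter), and NRF2 genes at 0.27 with every probe on its own. With no scaling androgen-induced genes stood at -1.23, DNA replication genes at -1.10 and oxidative phosphorylation at -0.86. Of the 126 changed genes that the rule named in this comparison, 48 had changes over 1.5 times smaller without background correction.

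The other 18 lists did not pass with WP1130. Ubiquitin and deubiquitinase genes had 7 up and 9 down of 22 (7 and 10 adjusted over the list alone; adjusted p = 0.70), with the stress-induced ZFAND2A at 4.54 and TNFAIP3, undetected with DMSO, at least 3.82-fold up. Of p53 target genes 6 of 16 rose and 7 fell (adjusted p = 0.43), with GADD45A at 3.24, CDKN1A at 2.67 and SESN1 at -1.30. Apoptosis regulators had 5 up and 4 down of 17 (adjusted p = 0.29), led by PMAIP1, a pro-apoptotic BH3-only gene, at 3.8 (other probe 0.77). Mitosis and G2/M genes had 11 up and 10 down of 32 (adjusted p = 0.18, but 0.049 with every probe on its own, as higher), with UBE2C at 1.07 and CENPF at -0.62. Genes linked to ERG-positive prostate cancer had 6 up and 12 down of 26 (adjusted p = 0.81). ETS transcription factors had 4 up and 6 down of 17 (adjusted p = 0.81), with ELF3 at 2.26 and ELK1 at -0.71, and the Wnt pathway 2 up and 7 down of 13 (0.45), with AXIN2 at 1.65 and FZD4 at -1.32. Cholesterol biosynthesis had 1 up and 8 down of 19 (adjusted p = 0.48), with SQLE at -0.95, and fatty acid synthesis 2 up and 6 down of 13 (0.54), with FASN at -0.93 and ME1 at 1.52. Hypoxia and glycolysis had 8 up and 9 down of 28 (adjusted p = 0.28), with ADM at 3.61 and LDHA at -0.62, and endoplasmic reticulum chaperones and ERAD 5 up and 7 down of 25 (5 and 6 adjusted over the list alone; 0.81), with CANX at -0.66. Ribosomal proteins had 3 up and 11 down of 35 (2 and 8 adjusted over the list alone; adjusted p = 0.54), with a median of -0.09 that was 0.29 with median scaling. Blood cell markers had 3 up and 0 down of 7 (adjusted p = 0.053), with CD68 at 1.71. As a list they passed as higher without background correction (adjusted p = 0.049), with median scaling (0.028), the authors' processed values (0.048), no filter (0.035), the mean of a gene's probes (0.013), every probe on its own (0.0017) and no scaling (0.018). They also passed without DMSO replicate 2 (median 0.32, adjusted p = 0.033), WP1130 replicate 1 (0.25, 0.038) or WP1130 replicate 3 (0.38, 0.040). All these calls used the preset correlation, and with an estimated one blood cell markers did not pass in the main design. Basal epithelium had 2 up and 1 down of 5 (3 and 1 adjusted over the list alone; adjusted p = 0.060), with LAMB3, undetected with DMSO, at least 3.99-fold up. That list passed as higher with the mean of a gene's probes (adjusted p = 0.029), without WP1130 replicate 1 (median 0.49, adjusted p = 0.032) and with no scaling (adjusted p = 0.013, with a median of -0.04). These calls used the preset correlation too, and with an estimated one basal epithelium did not pass in the main design. The counts up and down were 4 and 2 of 8 for mesenchymal and EMT genes (adjusted p = 0.14, but 0.028 with every probe on its own and 0.048 with no scaling), 2 and 2 of 6 for fibroblast and smooth muscle markers (0.48), 3 and 4 of 11 for neuroendocrine genes (0.865) and 1 and 1 of 5 for androgen-lowered genes (0.83). The list median and the test differed in sign for neuroendocrine, endoplasmic reticulum, ubiquitin, p53, hypoxia and ETS genes. Of the 16 lists that passed with the preset correlation 8 passed with an estimated one, and fry called 31 of the 34.

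The deubiquitinases named as targets of WP1130 changed unequally at the transcript level. UCHL1 rose by 1.07 ± 0.08 (limma adjusted p = 1.3e-08), USP14 fell by 0.75 ± 0.10 (adjusted p = 1.0e-05) and USP9X fell by 0.38 ± 0.10 (adjusted p = 0.0033), with a second USP9X probe at -1.26. USP5 fell by 0.26 ± 0.09 (adjusted p = 0.020), a call that was lost without DMSO replicate 1 (-0.22, 0.077), DMSO replicate 2 (-0.25, 0.052) or WP1130 replicate 3 (-0.19, 0.096). UCHL5 did not pass (0.00 ± 0.09, adjusted p = 0.97), and stood at -0.78 (adjusted p = 3.2e-06) with no scaling. With the ERG siRNAs these genes gave USP9X 0.01, USP5 -0.00, USP14 0.03, UCHL1 0.03 and UCHL5 -0.07, and none passed.

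The changes with WP1130 and with the ERG siRNAs were nearly unrelated across genes, with a Pearson r of 0.036 (Spearman 0.055) over 12744 genes and 51.5% of the same sign. Both arms have their own controls. Over the 1318 genes changed with both siRNAs r was 0.058, with 53.3% of the same sign. Genes that rose in both arms numbered 357 against 298 for independent lists, and genes that fell in both 600 against 453. Another 552 rose with the siRNAs and fell with WP1130 (504 for independent lists) and 237 did the reverse (267). The test of the difference between both effects called 6466 genes, 2521 higher and 3945 lower with WP1130 (39.0% higher, 63.6% with median scaling and 10.6% with no scaling). Among the positive differences were those of CRYAB, HSPA6 and HMOX1, undetected with DMSO, whose rises with WP1130 are known only as bounds. Among the negative ones was that of LRRTM4 (-3.38 ± 0.15), which rose after ERG knockdown. ATOH1 and HEPACAM2, which also rose after ERG knockdown, were lower with WP1130 by this test, but both were undetected with WP1130 and no size is given. TMPRSS2, up with the siRNAs, fell by 0.42 ± 0.09 with WP1130 (limma adjusted p = 0.00062), and ARHGDIB, the gene that fell most with the siRNAs, rose by 0.85 with WP1130 (adjusted p = 5.6e-06).

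**Figure D2:**
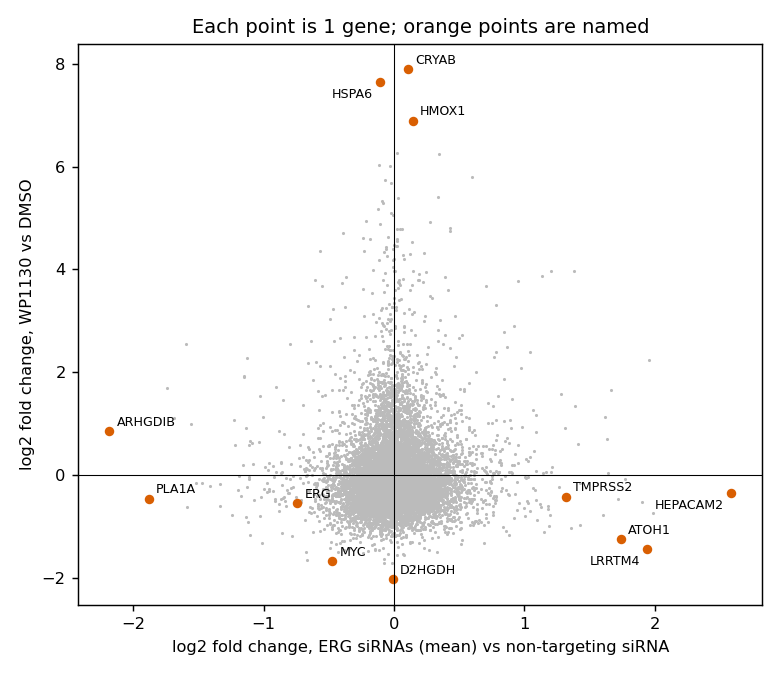
Log2 change with the mean of both ERG siRNAs (x axis) against the log2 change with WP1130 (y axis); each of the 12744 points is 1 gene and orange points are named. CRYAB (undetected with DMSO, at least 196-fold) lies far up with WP1130 and near 0 with the siRNAs, and HEPACAM2 at 2.59 lies far right.

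At the level of gene lists, 15 of 34 differed between both effects, 11 higher and 4 lower with WP1130, and 7 also with an estimated correlation. Androgen-induced genes were higher with the siRNAs and, at the preset correlation only, lower with WP1130 (adjusted p = 0.28 with an estimated correlation). Their difference had a median of -0.94 (adjusted p = 6.8e-05, and adjusted p = 0.083 with an estimated correlation), or -1.62 with no scaling. With an estimated correlation it passed with median scaling (adjusted p = 0.024), but not with no scaling (0.64). The same genes also differed between the controls, with a median of 0.29 for DMSO minus the non-targeting siRNA (adjusted p = 0.013, but adjusted p = 0.31 with an estimated correlation). Cholesterol biosynthesis differed with a median of -0.55, or -1.32 with no scaling (adjusted p = 0.0016, and adjusted p = 0.018 with an estimated correlation). Of its 19 genes 14 were lower and 1 higher with WP1130 than with the siRNAs. Notch pathway genes fell with the siRNAs and rose with WP1130, and their difference had a median of 0.47 (adjusted p = 0.00054, and adjusted p = 0.015 with an estimated correlation), or 0.28 without background correction, 0.84 with median scaling and 0.020 with no scaling. Heat shock (2.38), immediate early (3.17), NF-kB (1.11), ATF4 (0.67) and protease genes (1.18) were also higher with WP1130 with both correlations. Of these medians, NF-kB stood at 0.54 and proteases at 0.41 without background correction and immediate early genes at 2.09, while NF-kB stood at 0.58 and ATF4 at 0.11 with no scaling, and proteases at 2.05 with the authors' processed values. With an estimated correlation the Notch, ATF4 and protease differences were lost with median scaling (adjusted p = 0.076 for each) and with no scaling (0.18, 0.39 and 0.079), as was the cholesterol difference with no scaling (0.64).

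The other lists differed between both effects with the preset correlation only. Genes linked to ERG-positive prostate cancer were higher with WP1130 than with the siRNAs, with a median of 0.24 that was -0.48 with no scaling (adjusted p = 0.019, but adjusted p = 0.083 with an estimated correlation), and lost the call with median scaling (adjusted p = 0.095). Mitosis and G2/M genes were higher, with a median of 0.32 that was -0.45 with no scaling (adjusted p = 0.00054, but adjusted p = 0.098 with an estimated correlation), and lost the call with no scaling (adjusted p = 0.49). NRF2 genes were higher, with a median of 0.62 that was -0.05 with no scaling (adjusted p = 0.0013, but adjusted p = 0.098 with an estimated correlation), or 0.37 without background correction. Metallothioneins were higher, with a median of 0.67, or 0.053 with no scaling (adjusted p = 0.010, but adjusted p = 0.26 with an estimated correlation). Blood cell markers were higher, with a median of 0.42, or 0.14 without background correction, 0.17 with no scaling, 1.0 with median scaling and 0.92 with the authors' processed values (adjusted p = 0.032, but adjusted p = 0.13 with an estimated correlation). Oxidative phosphorylation was lower, with a median of -0.26, or -0.84 with no scaling (adjusted p = 0.0057, but adjusted p = 0.23 with an estimated correlation), and lost the call with median scaling (-0.020, adjusted p = 0.078). Ribosome biogenesis was lower, with a median of -0.46, or -1.14 with no scaling and -0.30 without background correction (adjusted p = 0.010, but adjusted p = 0.058 with an estimated correlation). Some of these lists also differed between the controls. The median of DMSO minus the non-targeting siRNA was -0.91 for mitosis genes, -0.51 for metallothioneins and 0.13 for oxidative phosphorylation. With an estimated correlation only the mitosis genes passed there. Such a difference between baselines may contribute and was not told apart from a difference between the effects.

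**Figure D3:**
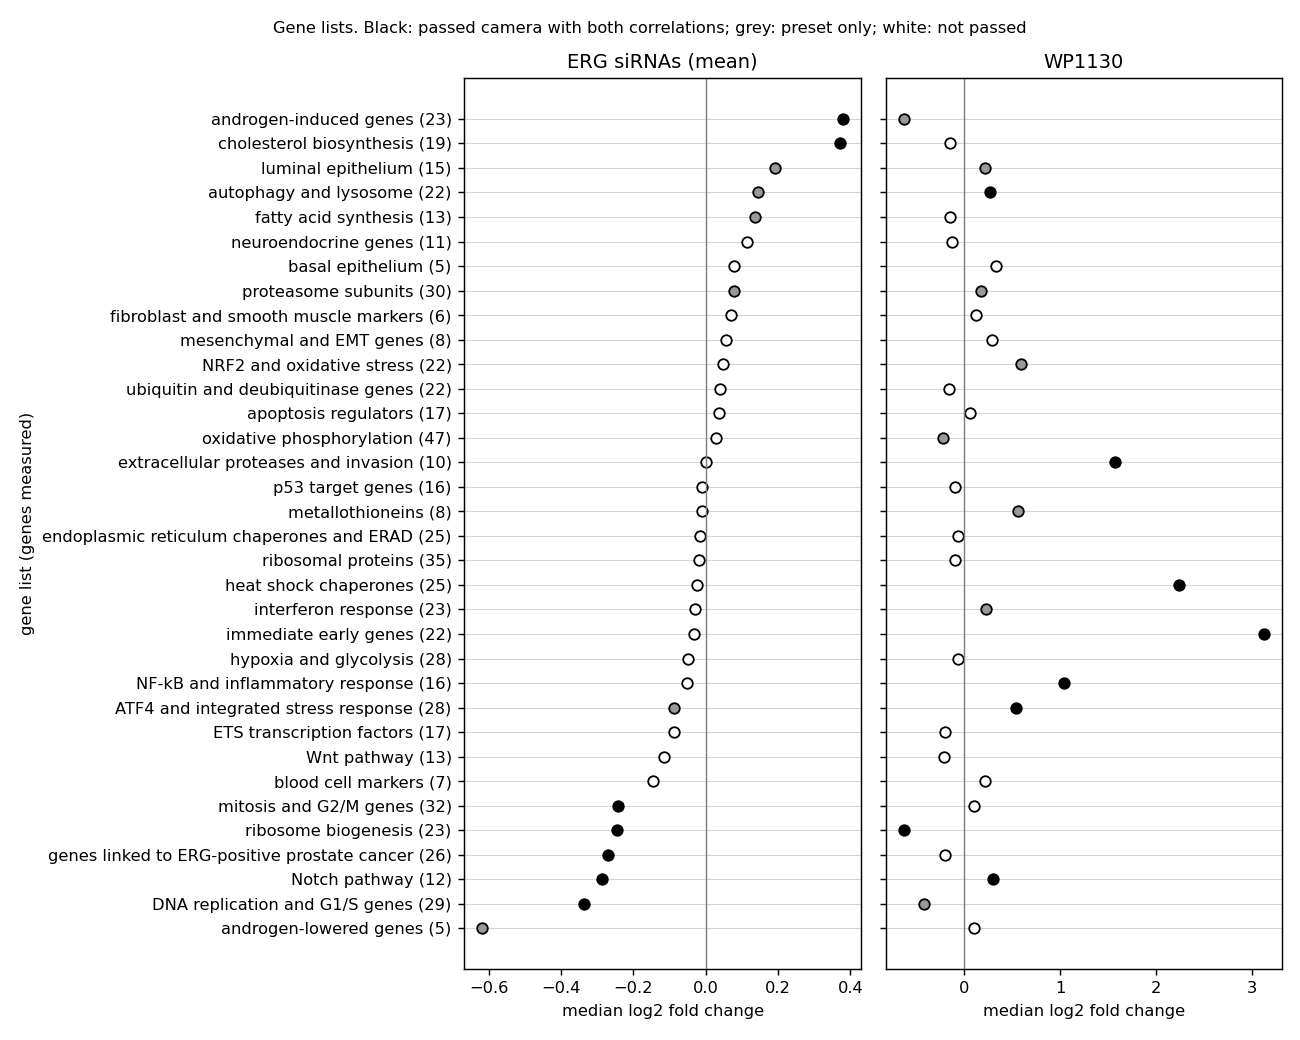
Median log2 change (x axis, with a different range in each panel) of each of the 34 tested gene lists (y axis, with the number of genes measured), with the mean of both ERG siRNAs on the left and WP1130 on the right; black points passed camera with both correlations, grey points with the preset one only, and white points did not pass. Androgen-induced genes stand at 0.38 on the left and at -0.62 on the right, and immediate early genes at 3.12 on the right, while ribosomal proteins, at -0.09 on the right, stood at 0.29 with median scaling.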

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

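Chosen only after the results were seen were the setting without scaling, the comparison of both controls, and the use of the other scalings, raw intensity, the count of androgen-induced members and each siRNA alone to weigh an explanation; the other tests in this part were planned.

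More genes fell than rose with WP1130, 4729 against 2790. Median scaling turned this split, with 62.1% of the changed genes up, so the balance may come from the choice of scaling. A lower RNA content of the treated cells was considered as well: mean raw intensity was 74.6% of that with DMSO, but RNA per cell was not measured. Background was also lower, with a mean of 103 with WP1130 against 111 with DMSO. Slide positions are not given, so a difference between slides cannot be told apart from an effect of WP1130 on raw intensity. Quantile normalization gives all arrays the same distribution, so a loss of RNA that is even across genes would largely be removed. Such an even loss is thus unlikely to give this split by itself. Raw intensity cannot decide on a loss that is uneven across genes, which stays open, as does the choice of scaling. The rises of chaperone genes are far larger than the shift of the median.

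Androgen-induced genes were higher with the ERG siRNAs and lower with WP1130, where the call was lost with an estimated correlation (adjusted p = 0.28) and with no scaling (0.064). The expression level of these genes does not account for it: their median lay at percentile 100 of 10000 random lists with the siRNAs (0.38, random lists -0.08 to 0.08) and at percentile 0 with WP1130 (-0.62, random lists -0.34 to 0.03). Scaling does not account for the difference at the preset correlation, with a highest adjusted p of 0.00021 over the other scalings. With an estimated correlation the call depended on the scaling. The adjusted p was 0.083 in the main design, 0.056 without background correction, 0.024 with median scaling and 0.64 with no scaling. A level peculiar to the non-targeting arrays, which both siRNAs share, was not told apart from an effect of ERG. The list was also higher with DMSO than with the non-targeting siRNA (median 0.29, adjusted p = 0.013, but 0.31 with an estimated correlation). Loss of ERG as the whole effect of WP1130 on these genes would raise them, as the siRNAs did. The fall of 17 of the 23 members with WP1130 goes against that, but the explanation stays open. The arms differ in treatment time and delivery, and with an estimated correlation this list's difference passed only with median scaling.

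Replication and mitosis genes were lower with the ERG siRNAs. The expression level of the genes was argued against, as their medians lay at percentile 0 of random lists. An off-target effect of 1 siRNA as the only cause is argued against, since both lists passed as lower with each siRNA (highest adjusted p = 4.53e-06). With an estimated correlation they passed as well, mitosis genes with ERG siRNA 1 at an adjusted p = 0.046. But both siRNAs share the same 3 controls. A level peculiar to those would lower both lists with each siRNA and stays open. A growth state of the cultures apart from ERG may contribute: the mitosis genes differed by -0.91 between DMSO and the non-targeting siRNA, which are both controls.

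The direct comparison of ERG siRNA 2 with ERG siRNA 1 called 15 genes. GULP1 differed by 1.07, with a fall only with ERG siRNA 1, so this change was not shared by both siRNAs. RLN1 differed by -0.96 while it rose with both. THBS1 differed by 0.65 while it fell with both. MIR92A2 differed by 0.72 and rests on a dim probe, with a bound of at least 1.45-fold. DDC differed by -0.59. SASS6 differed by -0.58.

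Of the 6200 probes past the filter that the gene table does not list, 459 changed with the mean of both ERG siRNAs (219 up, 240 down) and 2363 with WP1130 (979 up, 1384 down). With WP1130 the probes ILMN_1904238 (5.65) and ILMN_2143795 (5.51) rose most, and ILMN_1806845 (-1.67) and ILMN_1898691 (-1.64) fell most. Their transcripts were not analysed here.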

How the results depend on the processing

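The alternative without scaling was chosen only after the results were seen; the others were planned. A block for the slide was not run, since slide positions are not given in the sources used here, and where a value moved the cause was not tested. For gene lists the direction that turned is that of the test, and the value given is the median, which need not have turned with it. Without background correction ERG siRNA 2 against ERG siRNA 1 called 58 genes, and the correlations were 0.893 between both siRNAs and 0.0406 between WP1130 and the siRNAs. With median scaling directions turned for USP9X (-0.0086) and oxidative phosphorylation (-0.035) with the siRNAs. With WP1130 they turned for ADAM19 (0.18), CASP8 (0.032), MKI67 (0.091), XIAP (0.0080), ubiquitin genes (-0.031), ribosomal proteins (0.29), ETS factors (0.10) and the all-gene median (0.14). ERG with WP1130 was -0.20 and the correlation of WP1130 with the siRNAs 0.0185. The authors' values gave ERG -1.10 with siRNA 1 and -0.73 with WP1130, and correlations of 0.832 and 0.0317. Without the filter neuroendocrine (-0.046) and endoplasmic reticulum genes (-0.071) turned with WP1130 and the siRNA correlation was 0.848. With the stricter filter neuroendocrine genes (-0.21) turned and that correlation was 0.887. With the mean of a gene's probes p53 targets (0.068, siRNAs), RPS15 (-0.034), androgen-lowered (0.11), endoplasmic reticulum (-0.081) and ubiquitin genes (-0.17, all WP1130) turned. With every probe on its own 11945 probes passed with WP1130 and 9960 in the difference, with correlations of 0.838 and 0.0230. Directions turned there with the siRNAs for endoplasmic reticulum (-0.0067), p53 (0.017), oxidative phosphorylation (-0.0196), ETS (0.13) and autophagy genes (-0.0197), and with WP1130 for neuroendocrine (-0.16), endoplasmic reticulum (-0.092), ubiquitin (-0.22), oxidative phosphorylation (-0.068) and ETS genes (-0.14). With only the compared groups fitted ERG siRNA 2 against ERG siRNA 1 called 1 gene, and with trend and robust options 36. At 1.5-fold the counts were 356, 467 and 374 for siRNA 1, siRNA 2 and their mean, 298 for both and 3075 for WP1130. At an adjusted p under 0.01 they were 840, 1338, 1480 and, for both, 719. An estimated correlation left 7, 8 and 7 lists for the siRNA mean, WP1130 and the difference. With no scaling the siRNA counts were 842, 1187, 1402 and, for both, 674, ERG siRNA 2 against ERG siRNA 1 called 3, the correlation of WP1130 with the siRNAs was 0.0185 and the all-gene median -0.65. Directions turned there for oxidative phosphorylation (-0.0052) with the siRNAs, and with WP1130 for ACSL1 (-0.43), GPNMB (-0.062), HSPA5 (-0.19), NOP58 (-0.23), RPS15 (-0.12), RPS19 (-0.027), SLBP (-0.49), UCHL5 (-0.78), UGT2B17 (-0.43), androgen-lowered (-0.69), mitosis (-0.66) and endoplasmic reticulum genes (-0.74). The deviations of arrays from their group means were correlated between arrays of the same replicate number. These correlations were as low as -0.021 between the non-targeting siRNA and ERG siRNA 2. They were 0.047 to 0.14 between ERG siRNA 1 and ERG siRNA 2, where 3 of 3 arrays correlated best with their own number. With that number as a block the counts were 1641, 2315, 2533, 7522, 13 and 6471. With 1 array left out ERG siRNA 2 against ERG siRNA 1 called 9 to 14 genes, the siRNA correlation was 0.834 to 0.878 and that with WP1130 0.0308 to 0.0441. ERG was -0.94 to -0.56 with siRNA 1 and -0.59 to -0.50 with WP1130, and the all-gene median -0.126 to -0.116. Directions turned with the siRNAs within USP5 (-0.035 to 0.058), USP14 (-0.061 to 0.12), USP9X (-0.087 to 0.063), p53 (-0.045 to 0.034), immediate early (-0.054 to 0.0089) and ETS genes (-0.12 to -0.017), and with WP1130 within UCHL5 (-0.083 to 0.10).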

Other observations

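Every test in this part was chosen only after the results were seen, except the relabelling of arrays, which was planned.

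The DMSO and non-targeting siRNA controls differed from each other in more genes than the ERG knockdown did from its control. REG4, a secreted lectin, was higher with DMSO than with the non-targeting siRNA by 4.03 ± 0.12 (log2 ± SE, 3 arrays against 3), AOX1, an aldehyde oxidase, by 2.16, and the transcriptional repressor PRDM1 by 1.97. AQP12A (-2.08), the planar polarity gene PRICKLE1 (-1.88) and the muscle LIM protein gene PDLIM3 (-1.52) were lower, as was the metallothionein MT1H (-1.43). These genes were chosen after their values were seen. In all 3152 genes differed, 1671 higher and 1481 lower with DMSO, of which 42 and 87 by at least 2-fold.

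Mitosis and G2/M genes were lower with DMSO in 32 of 32 cases, with a median of -0.91 (adjusted p = 5.3e-36, and adjusted p = 0.00030 with an estimated correlation). DNA replication and G1/S genes had 14 lower and 1 higher (median -0.22, adjusted p = 4.2e-06, but adjusted p = 0.12 with an estimated correlation). Metallothioneins (6 of 8 lower, adjusted p = 9.8e-06) and androgen-lowered genes (4 of 5 lower, 0.013) were lower, and androgen-induced genes (11 of 23 higher, 0.013), proteasome subunits (7 of 30 higher, 0.013) and oxidative phosphorylation (16 of 47 higher, 0.0025) higher with DMSO. With an estimated correlation these adjusted p were 0.22, 0.13, 0.31, 0.30 and 0.30. The groups differ in transfection, vehicle and possibly time, and growth state could differ with any of these: the mitosis genes' -0.91 cannot tell them apart. The first principal component held 69.4% of the variance, the second 11% and the third 6.3%.

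The genes that both ERG siRNAs raised or lowered were looked up in the WP1130 comparison. Of the 713 that rose, 28.6% rose and 40.8% fell with WP1130 (camera adjusted p = 0.57, and adjusted p = 0.65 with an estimated correlation). Of the 605 that fell, 23% rose and 48.1% fell (adjusted p = 0.29, and adjusted p = 0.40 with an estimated correlation), against 21.4% and 36.3% of the other genes. Neither set differed from the other genes by this test, and a p above the threshold does not show that they did not differ. Fry, which does not compare a set with other genes, gave an adjusted p of 0.0055 for the first set and 4.3e-06 for the second, with medians of -0.09 and -0.19 against -0.12 for the other genes.

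Probes of the same gene passed in opposite directions for 143 genes with WP1130, 2 genes with the mean of both ERG siRNAs and 106 genes in the test of the difference between effects. Transcript variants, cross-hybridization and dim probes were not told apart.

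Relabelling the arrays gave a count as large as the real 2580 for the mean of both siRNAs in 1 of 84 splits, the real one, with a highest other count of 983 when the 3 ERG siRNA 2 arrays were taken as controls. For ERG siRNA 1 (1657, highest other 0), ERG siRNA 2 (2372, highest other 0), WP1130 (7519, highest other 0) and ERG siRNA 2 against ERG siRNA 1 (15, highest other 0), the 10 splits are too few to say more. For the difference between effects 1 of 100 splits reached 6466, with a highest other count of 6194; 14 of the splits kept WP1130 and DMSO apart and gave at least 5189, while those that mixed them gave at most 175. For genes changed with both siRNAs 3 of 100 splits reached 1318, with a highest other count of 1358. These 3 were the ones that kept the non-targeting arrays together, and splits that mixed them gave at most 2. Gene lists reached 13 for the mean of both siRNAs in 1 of 84 splits (highest other 11, median of the others 2). With WP1130 the 16 lists stood against a highest other count of 14, and a median of 9, in 10 splits, which are too few. Each other split also leaves WP1130 and DMSO arrays in unequal numbers on each side. Part of the WP1130 effect thus stays in, and these counts do not show what chance alone would give. For the difference 12 of 100 splits reached 15 lists, with a highest other count of 16 and a median of 8 among the others. But 14 of the splits kept WP1130 and DMSO apart, and whether the 12 were among these was not examined. The splits that mixed WP1130 and DMSO kept part of the WP1130 effect too, for the reason given. Chance was thus not excluded for the number of lists that differed, and this count does not measure it.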
